A study of Rattus norvegicus with 2 samples.

How the data were processed

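Total RNA was extracted with a kit for fibrous tissue and labelled with a one-colour low-input amplification kit, per the labels' protocols. The arrays were an Agilent rat expression design with 62976 spots, of which 58717 were non-control spots of 30367 probes. Most probes had 1 or 2 spots (13137 and 15840 probes), and 1390 had 10. Both arrays lay on the same slide and were read in the same scan, per the file headers, so slide and scan do not differ between the groups. The authors deposited the scanner output of each array, made with Feature Extraction 10.10.1.1 per the file headers. The deposited values used here are that software's processed spot intensities on a linear scale, per the file headers. The settings of its background treatment are not given in the sources used here, and the levels of the arrays differed, so they were scaled as described next. Other columns, also deposited by the authors, hold flags for spots well above background, saturated spots and outliers.

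Samples were grouped by their titles: 1 control arterial wall and 1 aneurysm. The processed intensity was put on the log2 scale and each array's 75th percentile over non-control spots, 621 in the control and 801 in the aneurysm library, was subtracted. Spots marked as outliers (484 and 573) were left out, and the spots of a probe were averaged. A probe was called well above background if at least as many of its spots carried that flag as did not. Probe names were taken from the file's accession, matched without version to a RefSeq gene table of a later assembly than the array's design, from which names only were used. Of the 30367 probes, 18006 matched 1 gene, 0 matched several and 12361 matched none; the matched probes covered 15159 genes. Unmatched probes are unnamed here. Genomic coordinates are not used here because the array and the table differ in build.

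Each gene was represented by its brightest probe well above background on at least 1 array, which left 11983 genes. Genes well above background on 1 array only (451 in the aneurysm library, 331 in the control) received a bound, the brighter value against the higher of the dim value and the lowest value of any probe well above background on that array. For 81 of these genes no bound was possible, leaving 11902. Genes at a difference of at least 2-fold were counted. Of 1906 genes with several probes well above background on both arrays, 0 had probes 2-fold apart in opposite directions; where probes of a named gene differ in sign the text says so. The spot error was computed from the spot-to-spot SD pooled over probes of like signal and the number of spots. The median spot SD among probes well above background was 0.06 in each library.

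Gene lists, 34 of them for vessel wall, inflammation and other cell types, and the rule for named genes were fixed before the data were examined. A list's median was ranked among 10000 random lists of the same size matched on mean signal in 20 bins, and a list stands apart below the 2.5th or above the 97.5th percentile; lists under 5 measured genes have values only. The rule names the 10 largest differences in each direction among genes well above background and unsaturated on both arrays, with locus-type names left out. It adds the 4 largest bounds in each direction, examples from up to 4 members per list with the largest absolute difference, and Ccl2, Ptgs2, Ptger2, Mmp9, Nfkb1, Acta2, Myh11 and Cd68. Some genes that the rule names are not reported here. Another 8 lists (hepatocyte secreted protein, hepatocyte enzyme and transporter, kidney, pancreas, heart, lung, hypothalamus and striatum) were written after the data had been seen.

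The code was tested on simulated arrays made from the control array with a spot SD of 0.12 and 200 changed genes. For the aneurysm against control comparison over 12022 genes, it called 100% of genes simulated 1.5 log2 units higher, 100% of those 1.5 lower, 100% of those 2.5 higher and 98% of those 2.5 lower, and 0 of 11822 unchanged genes. Of 40 random lists, 1 stood apart. The simulation holds no variation between animals, and its spot SD is the same at all signals. The measured spot SD pooled over probes well above background was 0.27 in the control and 0.16 in the aneurysm library. At the lowest control signals it was 0.57, so the simulated error rates do not hold for dim genes.

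Alternatives were normexp with an offset of 50, quantile normalization, median centring, the 75th percentile over probes well above background on both arrays, loess centring, spike-in scaling, 2 other filters on dim genes, the mean over probes, outlier spots kept, saturated spots left out, and thresholds of 1.5-fold and 4-fold. After the data had been seen, counts without the genes of the hepatocyte, brain and pituitary lists and list medians without members of a hepatocyte list were added, and the alternatives were also run on the 8 later lists and the unnamed probes. Normexp was planned on mean signals, a column not used here, and ran on median signals. Its offset is added to every signal, which shrinks the log2 differences of dim genes by construction. Spike-in scaling used the 7 of 10 spike-in probes well above background on both arrays. Work was done in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9) and R 4.3.3 with limma 3.58.1.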

Results

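Gene expression was measured in rat intracranial arterial tissue on 2 one-colour Agilent arrays. One library came from untreated intracranial arterial wall (1 array) and the other from an intracranial aneurysm lesion taken 3 weeks after induction (1 array). The series asks which genes differ between an induced aneurysm and normal arterial wall. With 1 array per group no difference below has a replicate check, no test across samples was possible and no p-value is given. The number of arrays limits the precision, so each difference describes these 2 libraries. Of the non-control spots, 74.7% were well above background in the control library and 76.4% in the aneurysm library, and no spot was saturated. Differences are log2 aneurysm minus control, and the value after ± is the spot error, computed from the spread between repeat spots within an array, which holds no animal-to-animal variation. A difference given as "at least" is a bound for a gene well above background on 1 array only. Where the dim value lay above the lowest value well above background, the bound equals the measured difference, as for Ptger2, Ube2t, Cyp4v3, Hrg and Gc. The same holds for Tpx2, Ccnb2, Plau, Htr1b, Cd8a, Hdc and Drd1. Such a bound is an estimate with a spot error (0.41 for Ptger2) and not a strict lower limit.

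The largest differences between the libraries were in genes typical of liver, which were lower in the aneurysm library. Of 33 ranked gene lists, 11 stood above random lists of matched signal, among them interferon response, elastic fibre and cell cycle, and 6 stood below, among them oligodendrocyte and pituitary. Genes of 1 list can vary together, which random lists leave out, so a place above or below all of them is not a test. Olr1, the endothelial receptor for oxidised LDL, was 5.07-fold higher (log2 2.34 ± 0.17), and Ptger2, the prostaglandin E2 receptor EP2, was at least 5.20-fold higher (log2 bound 2.38). With normexp background correction these were 1.25 and 0.46, so that Ptger2 was under 2-fold. The offset of normexp shrinks differences of dim genes by construction, so smaller values with it, here and below, can reflect the offset. Alb, which encodes serum albumin, had a 45.8-fold higher signal in the control library (log2 -5.52 ± 0.06). Across 11902 genes with a difference, 105 were at least 2-fold higher in the aneurysm library and 465 at least 2-fold lower, so that 81.6% of these genes were lower. This share was 93.2% with normexp, 71.1% with quantile normalization and 51.6% with spike-in scaling. Of the higher genes 51 were well above background on both arrays, and of the lower genes 236. In all, 95.2% of genes had a difference or bound under 2-fold, and the median over all genes was 0.001. A bound under 2-fold leaves a larger difference possible.

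Among genes well above background on both arrays, the 10 largest higher values included matrix and adhesion genes. Cilp, a cartilage matrix protein, differed by 1.91 ± 0.17 and Ibsp, which encodes bone sialoprotein, by 1.87 ± 0.41. Tac1, the precursor of substance P, differed by 1.59 ± 0.09. Vnn1, a pantetheinase, differed by 1.59 ± 0.18. The class I histocompatibility gene RT1-CE16 differed by 1.45 ± 0.06, a value that is uncertain because near-identical class I genes can share a probe. Tmem252 (1.40 ± 0.58) and Depp1 (1.38 ± 0.55) rested on 1 spot per array. The largest bounds after Ptger2 were those of the olfactory receptor gene Or12j4 (at least 3.34-fold), the ubiquitin-conjugating enzyme gene Ube2t (at least 3.33-fold) and Cyp4v3 (at least 3.30-fold). With normexp, 17 of the 22 named genes at least 2-fold higher that had a value were under 2-fold. Or12j4 was then at 0.39, Ube2t at 0.12, Cyp4v3 at 0.17, Ibsp at 0.48, Vnn1 at 0.44, Tmem252 at 0.40 and Depp1 at 0.47.

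Most of the largest lower values belonged to genes of hepatocyte products. Besides Alb, the bikunin precursor Ambp (-5.65 ± 0.18), the fibrinogen beta chain Fgb (-5.59 ± 0.18) and the liver fatty acid binding protein Fabp1 (-5.36 ± 0.18) were lower in the aneurysm library. Hsd3b5, a steroid dehydrogenase of liver, differed by -5.38 ± 0.35 and Serpina3c, a serine protease inhibitor, by -5.37 ± 0.35; with normexp these were -2.51 and -3.06. Mup4l3 (-5.51), Mup4l1 (-5.34), Mug1 (-5.48) and Mug1l1 (-5.39) belong to the major urinary protein and murinoglobulin families, whose close copies can share a probe, so these values are uncertain as to gene. Hrg, histidine-rich glycoprotein, and Gc, the vitamin D binding protein, were well above background in the control library only, at least 62.2-fold and 49.6-fold higher there. The other large bounds were Clca5 (at least 59.3-fold) and Iqcm (at least 41.8-fold), each measured by 1 spot per array. With normexp these 4 genes were still lower in the aneurysm library, but by less, with Hrg at -2.92, Gc at -3.09, Clca5 at -2.71 and Iqcm at -2.22. On 2 lists of hepatocyte genes written after the data had been seen, all 32 measured secreted protein genes and 23 of 24 measured enzyme and transporter genes were at least 2-fold lower, with medians of -4.07 and -2.72. With normexp these were 26 and 15 genes, with medians of -1.95 and -1.12, still below all random lists.

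**Figure D1:**
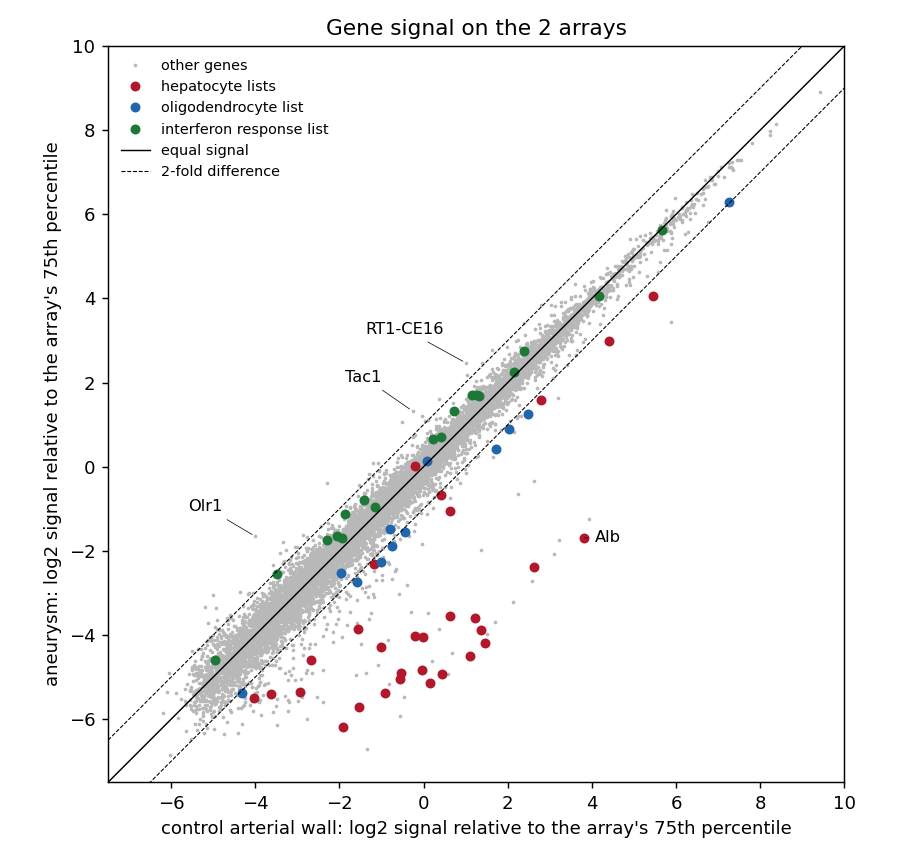
Normalised log2 signal of each gene well above background on both arrays, control library on the horizontal axis and aneurysm library on the vertical axis; solid line, equal signal; dashed lines, 2-fold difference. Most genes of the hepatocyte lists lie below the main cloud, with Alb at 3.82 in the control and -1.69 in the aneurysm library, while Olr1 lies above it.

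**Figure D2:**
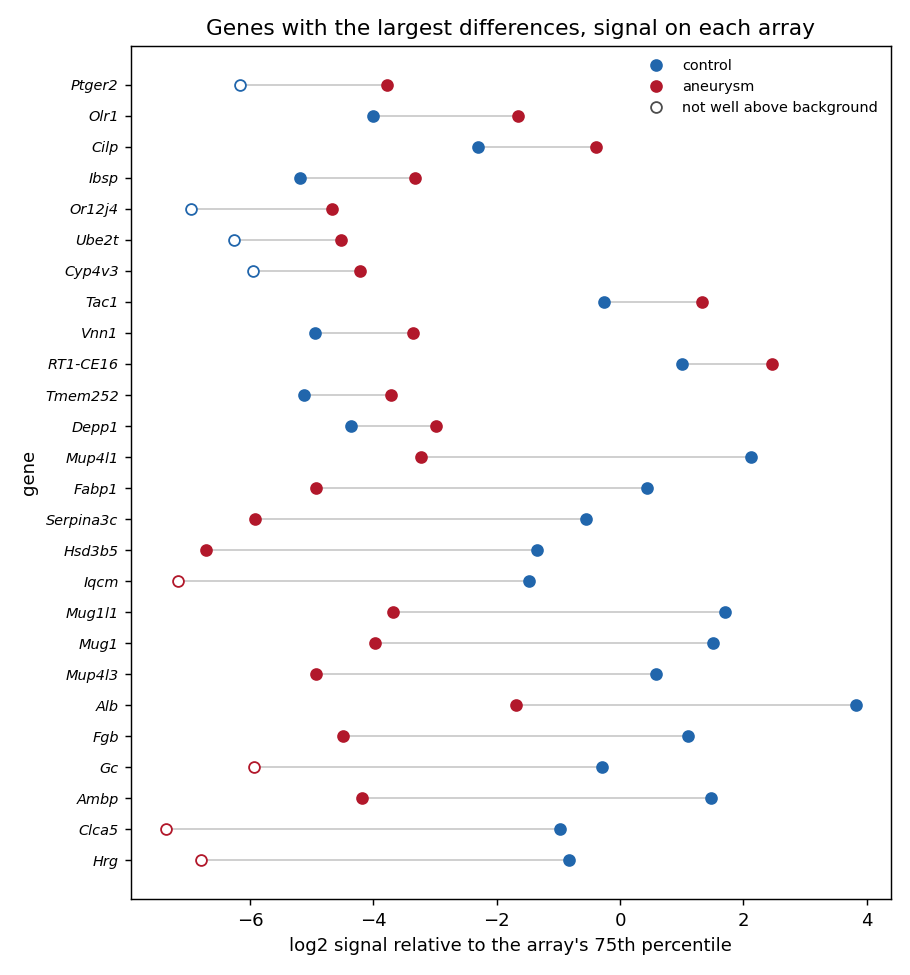
Normalised log2 signal on each array (1 array per group) for 26 of the genes with the largest measured differences or bounds; open circles, not well above background. Alb lies at 3.82 in the control library and at -1.69 in the aneurysm library.

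Chemokine, antigen presentation and interferon response lists stood above the random lists. Of 23 measured chemokine and cytokine genes, 19 were higher, with a median of 0.19 at the 99.6th percentile of random lists of matched signal. With normexp this median was 0.07, still above the random lists. In this list Spp1, which encodes osteopontin, differed by 1.29 ± 0.04, and Ccl2, the monocyte chemoattractant MCP-1, was 2.15-fold higher (1.11 ± 0.08, and 0.70 with normexp). Cxcl11 and Cxcl10, interferon-induced chemokines, differed by 0.75 and 0.75 (0.25 and 0.50 with normexp). All 15 antigen presentation genes were higher (median 0.31, percentile 99.99), among them RT1-Db1 (0.65), the peptide transporter Tap1 (0.63, and 0.29 with normexp) and RT1-Da (0.55). The interferon response list had 17 of 19 genes higher and a median of 0.38, above all 10000 random lists, with Ifit3 at 0.94 (0.51 with normexp), Usp18 at 0.73 and Isg15 at 0.62, none of them reaching 2-fold.

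Of the leukocyte lists, that of macrophages stood apart. The monocyte and macrophage list had 15 of 23 genes higher (median 0.20, percentile 99.9; median 0.07 with normexp), with the scavenger receptor Cd163 at 0.65 and C1qc at 0.51, while Cd68 was at -0.05 ± 0.06. The T, NK and B lymphocyte list lay within the random lists (median 0.09, but -0.16 with normexp and -0.12 with no filter on dim genes), with Cd8a at least 2.10-fold higher (0.05 with normexp) and Gzmb at -1.40. The neutrophil list (median -0.33, percentile 7.58) and the mast cell list (median -0.81, percentile 2.63, and -0.35 with no filter on dim genes) also lay within them. Lcn2, a neutrophil gene that liver also expresses, was at -2.03, and Hdc, histidine decarboxylase, had a bound of -1.82; with normexp these were -0.98 and -0.65.

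Genes of the NF-kappaB pathway and of prostaglandin signalling did not stand apart as lists. The NF-kappaB list had a median of 0.11 (percentile 90.4) over 15 genes, none 2-fold changed, with Nfkbia, the pathway's inhibitor, at 0.59 and the adhesion molecule Vcam1 at 0.46. Nfkb1 was not analysed here because no probe was matched to it. The prostaglandin list had a median of 0.08 (percentile 84.6) over 21 genes. In it Ptgs2, the inducible cyclooxygenase COX-2, was at 0.01 ± 0.18, Ptger3 at -0.88 ± 0.72 and the phospholipase Pla2g4a at 0.76, beside the bound of Ptger2. With normexp, Ptgs2 was at -0.16, Ptger3 at -0.44 and Pla2g4a at 0.19, and the medians of the NF-kappaB and prostaglandin lists turned to -0.0049 and -0.01.

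Of the matrix lists, those of elastic fibre and of proteases stood above the random lists. The elastic fibre list had 12 of 13 genes higher (median 0.43, above all random lists), with Mfap4 at 0.82, elastin Eln at 0.71 and fibrillin Fbn1 at 0.57. The matrix protease and inhibitor list (median 0.30, above all random lists) held the aggrecanase Adamts5 (1.13 ± 0.44), the urokinase Plau (at least 1.91-fold) and Mmp19 (0.85). With normexp the list median was 0.10, Adamts5 was at -0.04 and Mmp19 at 0.12. Mmp9 was not well above background on either array. The collagen and interstitial matrix list lay within the random lists (median 0.06, percentile 92.2), with Col8a1 at 0.99 and Postn at 0.99 ± 0.44. With normexp, Col8a1 was at 0.94 and Postn at 0.05.

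Among vessel wall cell types, fibroblast markers had the highest median. The adventitial fibroblast list had 8 of 9 genes higher (median 0.55, above all random lists), with Lum at 0.88 and Pi16 at 0.83. Contractile smooth muscle had a median of 0.14 (percentile 99.8), with Actg2 at 0.52, Acta2 at -0.01 ± 0.05 and Myh11 at 0.08 ± 0.05. Endothelium (median 0.16, percentile 97.4; median 0.0042 with normexp) and pericytes (median -0.03, percentile 39.7) lay within the random lists, with the endothelial co-receptor Eng at 0.99. The flow-responsive endothelial list had 12 of 13 genes higher (median 0.35, and 0.20 with normexp), with connexin gene Gja5 at 1.13 (0.92 with normexp) and the transcription factor Klf2 at 0.79. The vasoactive receptor and ion channel list had a median of -0.04, with the serotonin receptor Htr1b at least 2.20-fold higher, a difference that was 0.00025 with normexp.

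Cell cycle genes were higher, 23 of 24 of them, with a median of 0.40 above all random lists. Tpx2, a spindle factor measured by 1 spot per array, was at least 2.87-fold higher (spot error 0.62 log2 units). Ccnb2 was at least 2.20-fold higher, and Cdk1, the mitotic kinase, differed by 0.83 ± 0.04. With normexp the list median was 0.11, still above all random lists, Tpx2 was at 0.13 and Ccnb2 at 0.14. The apoptosis list had a median of 0.19 (percentile 98.3), with Cdkn1a at -0.42; its place above the random lists was lost under 6 of the 11 alternatives fixed in advance. The oxidative stress list lay within the random lists (median 0.14, percentile 96.8), with Xdh at 0.62 and Hmox1 at 0.46 (0.22 and 0.26 with normexp). The complement list also lay within them (median 0.11, percentile 95.9), with C1s at 0.97 against Cfi at -1.42 and C3 at -1.31, genes that hepatocytes express.

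Of the 12 lists for other cell types or quality, 6 stood below the random lists. The oligodendrocyte list had 8 of 12 genes at least 2-fold lower (median -1.13), including Mobp (-1.30) and Opalin (-1.26), which were at -0.99 and -0.95 with spike-in scaling. The pituitary list had a median of -1.13 over 6 genes, with Pomc, the precursor of corticotropin, at -2.97, growth hormone Gh1 at -2.23 and Cga at -1.41. The neuron list (median -0.27, percentile 0.47) held Tubb3 at -1.22 and Slc17a6 at -1.10, which were at -0.91 and -0.80 with spike-in scaling, where the list median was 0.04. The astrocyte list had a median of -0.37, with Agt, which liver also expresses, at -0.97. With spike-in scaling the astrocyte median was -0.06. That scaling shifts all genes alike, so it leaves ranks among random lists nearly unchanged by construction. Erythrocyte and platelet genes were all lower, 9 of 9 (median -0.48), with Hba-a1 at -0.95 and Alas2 at -0.999. Their median was -0.32 with quantile normalization and -0.29 with no filter, below the random lists each time, and -0.18 with spike-in scaling. Skeletal muscle genes had a median of -0.51 (-0.20 with spike-in scaling), with 6 of 7 lower, led by Pvalb at -2.42, while Ckm was at -0.77. The muscle actin gene Acta1 was higher, at 0.59 (0.13 at its lowest over the alternatives). The Schwann cell (median -0.02), leptomeninges (0.05) and choroid plexus (-0.02) lists lay within the random lists, although the choroid plexus gene Ttr, also a liver product, was at -1.42. The adipocyte list had 1 measured gene, Lpl, at 0.10 (-0.04 with normexp). The immediate early and heat shock list (median 0.00) and the reference list (median 0.05) lay within the random lists, with Fos at -0.39 and Sdha at 0.31; Gapdh was at -0.28, or 0.03 with spike-in scaling, and another of its probes at 0.27. Of the 16 lists within the random lists, 10 had medians that changed sign under at least 1 alternative fixed in advance, which were the lymphocyte, NF-kappaB, prostaglandin, pericyte, vasoactive receptor, Schwann cell, leptomeninges, choroid plexus, immediate early and reference lists.

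**Figure D3:**
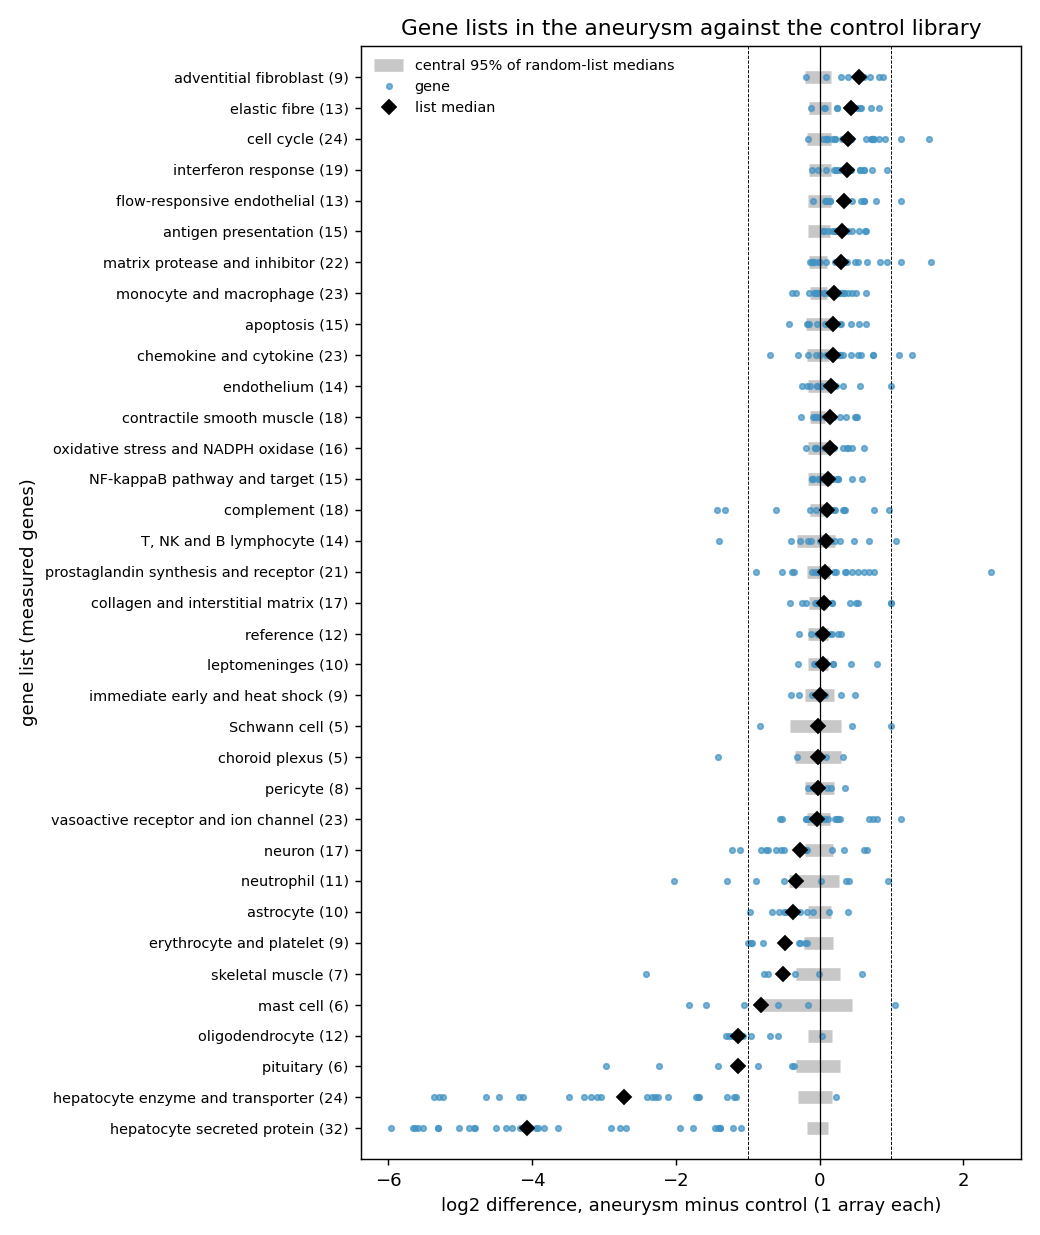
Log2 difference, aneurysm minus control, of each measured gene (blue) and the median (black) of each list of at least 5 measured genes, numbers measured in parentheses; grey, central 95% of 10000 random lists of matched signal. The fibroblast list is highest at 0.55, and the 2 hepatocyte lists, written after the data had been seen, are lowest at -2.72 and -4.07.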

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

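The tests of liver RNA, plasma protein genes, brain share, brain regions and shared tissue share were chosen only after the results they bear on had been seen. The tests on neighbouring spots and on loess centring were set before their own values were seen. Bootstrap intervals and reassignments below treat genes or spots as independent and hold no variation between animals.

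Among 8227 probes without a matched gene name, which no comparison above uses, 86 were at least 2-fold higher in the aneurysm library than in the control and 337 at least 2-fold lower. These counts were 4 and 91 with normexp, 133 and 311 with loess centring, 157 and 282 with quantile normalization, 231 and 227 with spike-in scaling, and 279 and 710 with no filter on dim probes. Among those well above background on both arrays, the lowest difference was that of probe A_64_P123338, at -5.30 (-4.44 with normexp), and the highest that of probe A_44_P636717, at 2.75 (1.30 with normexp). The lowest bound was that of probe A_64_P033949, at -6.19 (-3.09 with normexp), and the highest that of probe A_64_P026763, at 2.90.

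Liver transcripts were higher in the control library. A change of plasma protein genes alone is argued against by hepatocyte enzymes and transporters, whose median was -2.72 (95% bootstrap interval over genes -3.61 to -2.06; -1.12 with normexp, still below all random lists), and a fault of 1 array region by 406 spots of other genes beside the hepatocyte spots, whose median was 0.0094 (-0.02 to 0.04). An earlier test of the region, asking that over 95% of lower hepatocyte probes with several spots be 2-fold lower at every spot, found 49 of 52 (94.2%) and did not decide; the test on neighbours was added after it. A candidate explanation is RNA of liver in the control library: at least 95.8% of the measured genes of each hepatocyte list were 2-fold lower (26 of 32 and 15 of 24 with normexp). The plasma protein genes Tf, Ttr and Alb differed by -1.39, -1.42 and -5.52. Tf and Ttr stayed high in the aneurysm library (4.06 and 2.99, against -1.69 for Alb). Because both stayed high where Alb was low, the differences of Tf and Ttr need not reflect liver. Ttr is also a choroid plexus gene, although the choroid plexus list lay within the random lists (median -0.02). The source of these 2 differences was not tested. The lists were written after many of these values had been seen, so this explanation cannot be told apart from other sources. Of the 56 measured genes, 30 were well above background in the aneurysm library too and 1 is also in a fixed list; how such RNA would have entered, and any biological difference between aneurysm and normal wall, stay open.

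Oligodendrocyte and pituitary markers were lower in the aneurysm library. A single smaller share of brain tissue is argued against by the oligodendrocyte median, which lay below that of neurons (difference -0.86, 95% bootstrap interval -0.97 to -0.35). Different brain regions beside the vessels may contribute: the hypothalamus list had a median of -1.11 and the striatum list 0.45 (difference -1.56, interval -2.13 to -0.84). With normexp these medians were -0.64 and 0.33. These lists were built around genes whose values had been seen, and with 1 array per group the difference in tissue cannot be told apart from the difference in disease state.

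Fibroblast, elastic fibre, interferon and cell cycle lists were higher in the aneurysm library. A lower share of non-vascular tissue is argued against as the whole cause only if it raised all wall genes alike. The medians of the 4 wall cell types ranged over 0.58, against 0.36 at the 95th percentile of 10000 reassignments of their genes. Tissue that itself holds vessel cells would not raise them alike, and the test cannot decide on that case. That test holds no elastic fibre, interferon or cell cycle list, so a part from tissue share stays open for these as well. A bias that follows signal is argued against as the whole cause by the ranking itself, as all 4 lists stood above random lists of matched signal. After loess centring the lowest of the 4 medians was 0.37 and all stayed above the random lists. That rank adds little, because matched random lists would share such a bias before and after centring. The cell cycle median was 0.11 with normexp. A difference between aneurysm and normal wall stays open as a hypothesis, as does a difference between 2 animals or dissections.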

How the results depend on the processing

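The counts without list genes and the list medians without members of a hepatocyte list were chosen after seeing the data; the other alternatives here were planned. With 1 array per group no replicate could be left out. No paired analysis was possible because each group has 1 array and no test. No spot was saturated, so leaving saturated spots out removed no value and says nothing about stability. Of 33 ranked lists, 26 kept their side of the random lists under all 11 alternatives fixed in advance. Several of these alternatives could hardly move a rank. Median centring, the 75th percentile over probes well above background on both arrays, and spike-in scaling shift all genes alike. Ranks can then change only slightly, through bounds gained or lost. Keeping outlier spots added back few values (484 and 573 spots). The count of 26 therefore overstates stability. Leaving out hepatocyte list members took a gene from the choroid plexus list alone, which then had too few genes to rank, and says nothing about the other lists. Of 56 named genes at least 2-fold apart, 55 kept their direction. The exception was Adamts5, at -0.043 with normexp. Spike-in scaling moved the median of all genes to 0.31, so the neuron median of 0.036 with it is still below that of all genes. The neuron list kept its side of the random lists, which follows nearly by construction from a shift shared by all genes. Where no cause is named below, the cause was not tested.

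Higher and lower counts were 506 and 1003 at 1.5-fold and 2 and 178 at 4-fold, by construction of the threshold. They were 14 and 193 with normexp, which changed the background treatment and the signal column together and whose offset shrinks differences of dim genes. They were 51 and 237 with only genes well above background on both arrays, where fewer genes are counted. No filter on dim genes, which counts more, gave 182 and 758. The higher count was 165 with quantile normalization and 311 with spike-in scaling. The apoptosis median no longer stood apart with normexp (0.062), quantile (0.16), loess (0.12), spike-in scaling (0.46), only genes on both arrays (0.10) or no filter (0.15). The mast cell list had too few genes on both arrays to rank, and its median stood apart with normexp (-0.56), loess (-0.67), spike-in scaling (-0.50) and the mean over probes (-0.81). The complement median did so with normexp (0.12), quantile (0.22) and loess (0.14), the collagen median with quantile (0.15) and loess (0.10), the oxidative stress median with quantile (0.17) and no filter (0.11), the reference median with quantile (0.17), and the endothelium median with only genes on both arrays (0.16). Dim signals limit precision: the spot SD was 0.57 in the control library at its lowest signals and 0.05 at its highest.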

Other observations

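All tests and lists in this part, apart from the skeletal muscle list, were chosen, and the alternatives run on them, after the data had been seen.

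Neuropeptide and receptor genes of different brain regions moved apart. Of 16 measured hypothalamus genes, 10 were at least 2-fold lower in the aneurysm library, among them Avp (vasopressin, -2.44), Nkx2-1 (-1.40), Npy (-1.03) and Trh (bound -1.88). Of 13 measured striatum genes, 10 were higher, among them the dopamine receptor Drd2 (0.88, but 0.44 with the mean over probes), the enkephalin precursor Penk (0.83) and Adora2a (0.52). Drd1 had a bound of -2.72 and Pdyn was at -0.50. With normexp, 3 of the 16 hypothalamus genes were at least 2-fold lower and 10 of the 13 striatum genes were higher, with Nkx2-1 at -0.66, Npy at -0.96, Trh at -0.64, Drd1 at -1.14, Drd2 at 0.41 and Adora2a at 0.30. With spike-in scaling, 5 hypothalamus genes were at least 2-fold lower, and Npy was at -0.72. These genes were named after their values had been seen.

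Markers of other peripheral organs did not follow the liver genes. The kidney list had a median of -0.11 over 7 measured genes, pancreas 0.05 over 6, heart -0.12 over 8 and lung -0.20 over 6, and all 4 lay within the random lists. The sign of each of these medians changed under at least 1 alternative: spike-in scaling gave 0.19 for kidney, 0.19 for heart and 0.10 for lung, and normexp gave -0.20 for pancreas. Leaving out the genes of the hepatocyte, brain and pituitary lists left 102 genes at least 2-fold higher and 387 at least 2-fold lower in the aneurysm library. These lists hold only some genes of each tissue: of 97 genes at least 8-fold lower, 33 are in the hepatocyte lists. The counts that remain therefore do not show how many lower genes come from other tissues.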
